A study of Mus musculus with 36 samples.

How the data were processed

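Ribosome-bound RNA of cortical pyramidal neurons was sequenced from 36 libraries of mouse cortex, per the labels. The labels name libraries from a strand-preserving TruSeq mRNA kit, read as pairs of 100 bp on an Illumina HiSeq instrument, and a stated depth of 15 M reads per sample. The deposited files hold whole-number counts per gene for each library, not normalized, with 55470 gene identifiers in each file. The submitters' processing notes list Trimmomatic 0.39, FastQC, HISAT2 2.2.0, StringTie 2.1.3, Salmon 1.4 and DESeq2 with the mm10 build. Which of these tools made the counts, and whether the counting used the strand of the reads, was not given in the sources used here. A symbol was found for 55143 identifiers in a table of gene names, and a position for 55229 in the GENCODE vM21 annotation of mm10. Rows without a symbol held 0.041% of all counts and were kept under their identifiers.

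Groups, replicate numbers and cohorts were taken from the labels. Cohort 1 held 17 libraries and cohort 2 held 19 libraries, and each cohort had its own naive mice. The labels do not tie a library to a named animal, so p-values measure the spread between libraries. Libraries of the same group were compared in 92 pairs by a chi-square test of their counts. The lowest chi-square per degree of freedom was 1.54 and the highest was 104.69, so no library was treated as deposited more than once. Total counts ran from 0.884 to 3.52 M per library, and the precision of each gene follows from these totals.

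Counts were fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with robust estimation and TMM scaling. The model had 8 cells, made of genotype, treatment and cohort, and left 28 residual degrees of freedom. The low-count filter of edgeR left 11341 genes. Swim groups were compared only with naive mice of their own cohort, so the responses of the genotypes shared no library. Adjusted p-values are Benjamini-Hochberg values over the genes tested in each of 11 comparisons, with a threshold of 0.05 and no fold threshold. Fold changes are log2 values with a standard error (SE), and CPM values are counts scaled to the TMM library size with a standard deviation (SD). The SE is the absolute log2 fold change divided by the square root of the F statistic of the test. It can be too small for genes with few counts. The direction of a genotype effect is Shank3 over WT, and that of a swim response is swim over naive.

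The 25 gene lists were fixed before the data were examined, 11 for responses and pathways and 14 for cell types. Of these, 20 had enough measured members and were tested with camera from limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. This gave 220 list tests. Markers of oligodendrocyte precursors, endothelial and mural cells, hippocampal neurons, choroid plexus and blood had too few measured members and were not tested. The values printed for a list are the median log2 fold change of its measured members. The genes named were set by a rule written before the data were examined. The rule took the 10 rising and 10 falling genes with the smallest p among those past the threshold with a mean log2 CPM of at least 1, leaving out provisional gene names, and the 4 members of each list with the smallest p. It also took Shank3 in each comparison, the 5 genes with the smallest p where fewer passed in the naive genotype effect and the interactions, and genes past the threshold within 10 Mb of Shank3. Gm15609 was chosen after its values were seen.

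After the values were seen, rows were classed by what the annotation places on the opposite strand. An antisense row and a protein-coding row whose exons overlap on opposite strands made a pair. The pair share is the percent of the counts of such pairs that lay on the protein-coding rows, computed per library. Its centred log2 value was added to the model as a covariate in an alternative, which is called the fit with the pair share. The common biological coefficient of variation was 24.2% without it and 13.3% with it. The slope on the pair share passed the threshold for 62.9% of the genes tested. TMM factors ran from 0.498 to 1.818 and had a Spearman rho of 0.98 with the pair share. CPM values and fold changes between groups that differ in pair share therefore depend on this scaling. The pair share overlaps the swim groups, so this covariate also removes effects of the swim that run along with it.

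A glial score per library was the mean centred log2 CPM over the measured members, which were few, of the astrocyte, oligodendrocyte, microglia and endothelial lists. Differences of pair share, depth and glial score between groups were tested with exact two-sided permutation tests of the mean. Intervals on ratios of counts are exact 95% binomial intervals and cover counting error only.

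The fits were checked on simulated counts of 11341 genes, of which 67 changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For genes changed 2-fold, 26.9% were recovered for the WT response at 1 h, 32.8% for the WT response at 4 h and 65.7% for the genotype effect at 4 h. For genes changed 4-fold, 80.3%, 92.4% and 95.5% were recovered in the same comparisons. The interactions recovered fewer, at 47% at 1 h and 62.1% at 4 h for 4-fold changes. In simulated libraries that differed only along the pair share, the WT and Shank3 responses at 4 h gave 5064 and 6174 calls without the covariate and 0 calls with it. Each other comparison, the responses at 1 h among them, gave 0 calls without the covariate. The slopes and the spread of these simulated libraries came from the fit with the pair share to the real libraries. The 0 calls with the covariate were thus built in and do not test it. The calls without it only show what the fitted slopes would give.

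The alternatives fixed before the data were examined were an additive cohort term, fits on the libraries of each comparison alone, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no low-count filter, genes with a mean log2 CPM of at least 1 only, the replicate number as a block, the glial score or the Xist level as covariate, the estimated list correlation, each cohort alone, each cell alone, and each library left out in turn. The pair share covariate, the restriction to genes with no gene on the opposite strand, and the removal of libraries with over 10% of counts on a ribosomal RNA row were added after the values were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for summaries and figures.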

Results

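Ribosome-bound RNA was measured in the cortex of Shank3(∆C/+) mice, which carry a mutated copy of the gene for the postsynaptic scaffold protein Shank3, and of their WT littermates. The RiboTag method tags the ribosomal protein Rpl22 with an HA epitope in cells that express Cre, here under Camk2a in pyramidal neurons, and pulls down ribosomes with their RNA through the tag. Mice were left naive or were killed 1 h or 4 h after a forced swim in water at 25 °C, a stressor whose length the labels give as 5 min in one field and 6 min in another. Cohort 1 held 3 naive WT, 3 naive Shank3, 6 WT and 5 Shank3 libraries at 1 h. Cohort 2 held 4 naive WT, 4 naive Shank3, 5 WT and 6 Shank3 libraries at 4 h. The 1 h groups were all in cohort 1 and the 4 h groups all in cohort 2. The sex of the mice was not given in the sources used here. Total counts ran from 0.884 to 3.52 M (mega) counts per library with a mean of 1.58 ± 0.553 M counts (SD, n = 36). This was 5.89% to 23.47% of the stated 15 M reads. The WT libraries at 4 h held 2.16 ± 0.789 M counts (SD, n = 5) against 1.18 ± 0.286 M (n = 4) in naive WT mice of the same cohort (exact two-sided permutation p = 0.0317). Mean totals of the other swim groups were also above those of their naive mice. There the exact permutation p was 0.0667 for Shank3 at 4 h, 0.1667 for WT at 1 h and 0.0893 for Shank3 at 1 h. A ribosomal RNA row held 38.58% and 13.52% of the counts in Shank3 naive replicates 7 and 6 of cohort 2 and 10.54% in WT 1 h replicate 5.

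Most counts lay on rows that the annotation places opposite an exon of another gene. Rows with an exon opposite another gene were 16.4% of the rows and held 75.7% of the counts. This class holds both rows of each pair, and the antisense rows paired with coding rows held 22.7% of all counts. The row of Gm20721 held 2267039 counts over all libraries and that of Gnas, the G protein subunit gene on the other strand, 17385. The row of Gm14703 held 593396 counts against 29987 for Syp, the gene of the synaptic vesicle protein synaptophysin. Among 999 antisense and coding pairs with at least 1000 counts, the antisense row was above its coding partner in 757, and the median antisense percent was 82.0%. Values of genes with an exon opposite another gene are therefore uncertain, since counts of both strands cannot be told apart without the counting setting. Rows with no gene on the opposite strand held 19.2% of the counts. If the counting used the opposite strand, these may be residual counts, so their values are uncertain as well. Of the 11341 genes tested, 5241 had an exon opposite another gene and 4822 had no gene on the opposite strand.

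The pair share, the percent of these pair counts on the coding rows, was higher in swim than in naive libraries, past 0.05 in 3 of the 4 comparisons. In WT mice of cohort 1 it was 10.8% ± 0.185 (SD, n = 3) in naive and 14.4% ± 2.09 (n = 6) in 1 h libraries (exact two-sided permutation p = 0.0357). In WT mice of cohort 2 it was 13.2% ± 1.4 (n = 4) in naive and 23.2% ± 5.32 (n = 5) in 4 h libraries (exact permutation p = 0.0159). In Shank3 mice it was 11.3% ± 0.565 (n = 3) and 14.0% ± 1.81 (n = 5) in cohort 1 (exact p = 0.0714), and 13.1% ± 1.48 (n = 4) and 25.5% ± 7.23 (n = 6) in cohort 2 (exact p = 0.019). The genotypes gave exact p values of 0.3, 0.8286, 0.7619 and 0.5303 for naive cohort 1, where 3 against 3 libraries cannot go below 0.1, naive cohort 2, 1 h and 4 h. The glial score rose from -0.128 ± 0.18 (SD, n = 4) to 0.395 ± 0.114 (n = 5) in WT mice at 4 h (exact p = 0.0079) and from -0.22 ± 0.227 (n = 4) to 0.32 ± 0.158 (n = 6) in Shank3 mice (exact p = 0.0048), each the smallest p these group sizes can give. At 1 h the exact p values of the glial score were 0.1667 in WT and 0.4107 in Shank3 mice. Genes with no gene on the opposite strand also rose at 4 h, with a median log2 fold change of 0.576 in WT and 0.619 in Shank3 mice. The rise of the score is thus not shown to come from glial RNA. The plot of pair share by group shows each library.

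**Figure D1:**
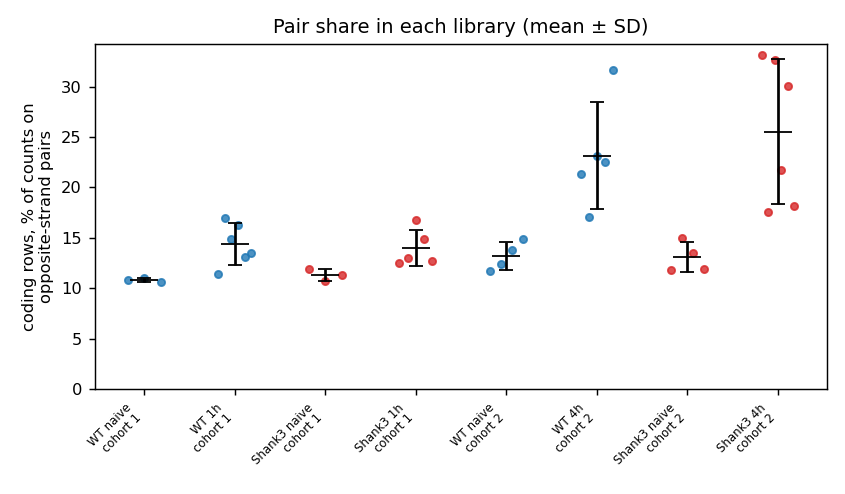
Pair share in percent (vertical axis) for each of the 36 libraries, by group and cohort (horizontal axis). Naive libraries lie between 10.65% and 14.98%, and the 4 h libraries between 17.04% and 33.09%.

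The Shank3 row itself was low in all libraries and did not mark the mutation. The row, ENSMUSG00000022623 on chromosome 15 from 89499623 to 89560261 in mm10, is a count over the whole gene with an exon opposite another gene, so it does not test the deleted part. Naive WT libraries held 4, 10, 6, 5, 6, 8 and 6 counts of Shank3 and naive Shank3 libraries 10, 9, 13, 12, 30, 13 and 9. At 1 h the WT libraries held 9, 20, 14, 16, 5 and 15 counts and the Shank3 libraries 20, 11, 34, 14 and 14. At 4 h the WT libraries held 14, 20, 41, 34 and 118 counts and the Shank3 libraries 146, 43, 130, 32, 89 and 19. The log2 fold change of Shank3 over WT mice was 0.83 ± 0.314 (SE) in naive, 0.28 ± 0.297 at 1 h and 0.85 ± 0.235 at 4 h, with edgeR adjusted p = 1 in each. Over all conditions it was 0.70 ± 0.183 with an edgeR adjusted p of 0.59. Gm15609, a lincRNA row chosen after its values were seen, lies on the minus strand from 89520096 to 89523677, opposite exon 10 of Shank3, where it covers the 271 bases from 89521103 to 89521373. Its log2 fold change over all conditions was 0.68 ± 0.134 (edgeR adjusted p = 0.0577), and 0.72 with an adjusted p of 3.34e-10 in the fit with the pair share. The adjusted p of Gm15609 was as high as 1 over 15 alternatives, of which 6 passed.

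**Figure D2:**
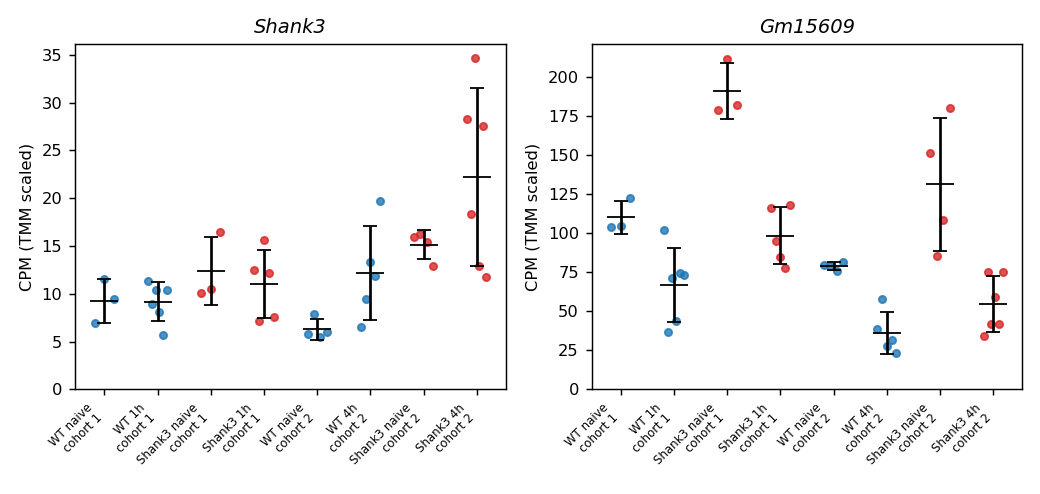
TMM-scaled CPM of Shank3 and Gm15609 in each library (points), by group and cohort, with bars for the mean ± SD. Gm15609 in naive cohort 1 was 110.3 ± 10.5 CPM in WT and 190.9 ± 17.98 CPM in Shank3 mice (SD, n = 3 each).

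**Figure D3:**
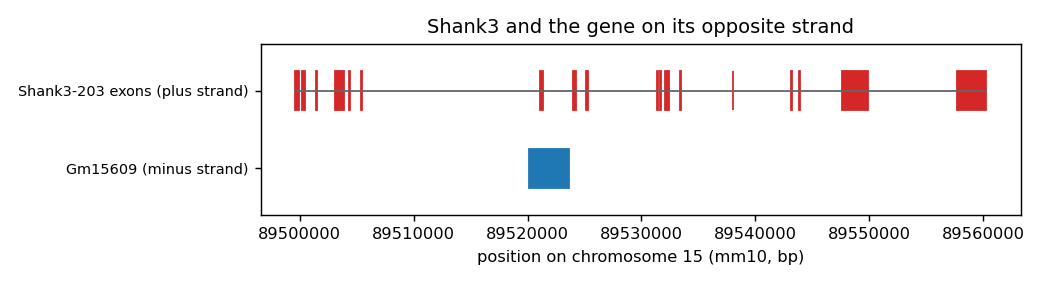
Map of the Shank3 locus on chromosome 15 in mm10, with the 22 exons of a Shank3 transcript on the plus strand and the span of Gm15609 on the minus strand. The horizontal axis is the position in bases, and exon 10 is the exon opposite Gm15609.

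The genotype effect in naive mice addressed whether the mutation alters ribosome-bound RNA without stress. Ncam2, the gene of a neural cell adhesion molecule (ENSMUSG00000022762, chromosome 16 from 81200697 to 81626828), was higher in Shank3 mice by a log2 fold change of 2.43 ± 0.403 (SE, edgeR adjusted p = 0.00736) and was the only gene of 11341 past the threshold in this fit. The fit with the pair share called 3, limma 2 and the fit with no filter 7 genes, and 0 passed with an additive cohort term. Ncam2 rested on few counts, and its log2 fold change was 3.93 without WT naive replicate 1. It was not in the fit on genes with no opposite-strand gene, so a gene on the opposite strand may bear on its counts. Naive Shank3 mice of cohort 1 held 19 counts of Ncam2 in 3 libraries and WT mice 1, a ratio of 15.0 with a 95% interval of 2.39 to 623.41. In cohort 2 they held 44 and 19 counts, a ratio of 2.29 with an interval of 1.31 to 4.15. The SE of Ncam2 does not reflect the width of these intervals and is too small. Ncam2 also differed between the naive mice of the cohorts, by 1.79 ± 0.426 for cohort 2 over cohort 1 (edgeR adjusted p = 0.02). That comparison was chosen after the values were seen. Acat2, an enzyme of acetyl-CoA metabolism, had a log2 fold change of 1.38 ± 0.291 (adjusted p = 0.135), and Mindy3, Atp6v0b and Sf3b1 had adjusted p = 0.534. An unadjusted p under 0.05 was reached by 539 genes. No gene passed without WT naive replicate 2, Shank3 naive replicate 2 or Shank3 naive replicate 5, nor in either cohort alone, while 6 genes passed without WT naive replicate 3 and 2 without WT naive replicate 4.

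At 1 h after the swim no gene differed between Shank3 and WT mice by edgeR, DESeq2 or limma (0 in each), with 205 genes at an unadjusted edgeR p under 0.05, and 1 gene passed with no filter. The nuclear genes of oxidative phosphorylation were lower in Shank3 mice as a list (median log2 fold change -0.25, 59 members, 0 past the threshold, also adjusted over the list alone), with a camera adjusted p of 3.66e-05. Cytosolic ribosomal protein genes had a median of -0.20 over 64 members, with 0 past the threshold (camera adjusted p = 0.00179). With an estimated correlation both adjusted p values were 0.886, and in the fit with the pair share they were 0.00174 and 0.0653. Without WT 1 h replicate 2 the medians less that of all genes were -0.11 and -0.08 and neither list passed.

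At 4 h after the swim Slc7a11, the cystine and glutamate exchanger of the plasma membrane (ENSMUSG00000027737, chromosome 3 from 49892526 to 50443614), was higher in Shank3 mice by a log2 fold change of 4.91 ± 0.549 (SE, edgeR adjusted p = 1.47e-06). It was at 276.9 ± 41.1 CPM in Shank3 mice (SD, n = 6) and 9.02 ± 3.59 CPM in WT mice (n = 5), with each of the 6 libraries above each of the 5. Naive mice of the cohort were at 23.8 ± 15.7 CPM in WT and 36.4 ± 5.90 CPM in Shank3 mice (n = 4 each). At 1 h, 3 libraries of both genotypes also had high Slc7a11 values, with 188.3 and 238.1 CPM in WT replicates 2 and 4 and 249.0 CPM in Shank3 replicate 3, against 33.99 to 61.31 CPM in the others. Whether Slc7a11 follows the Shank3 mutation or another difference between the animals, such as a linked or strain variant, was not tested. Slc7a11 was not in the fit on genes with no opposite-strand gene, so a gene on the opposite strand may bear on its counts. No other gene passed at 4 h in this edgeR fit, with 228 genes at an unadjusted p under 0.05. The count was 3 in the fit with the pair share, 5 with no filter and 2787 by limma with quality weights.

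Genes induced by neuronal activity were higher as lists in Shank3 than in WT mice at 4 h, but chance could not be excluded. Of 100 splits of these libraries, the real one among them, 5 gave a camera p as small for any list. The median smallest p of the other splits was 5.64 on the -log10 scale. Camera p values with the preset correlation thus come out small here in arbitrary splits. Of the delayed activity-regulated genes, 23 of 27 had a log2 fold change above 0, with a median of 0.29 (camera adjusted p = 1.44e-08, and adjusted p = 0.00303 with an estimated correlation). Examples were Nptx2, a synaptic pentraxin, at 0.83 ± 0.332 (SE), Nr4a3 at 0.48 ± 0.232 and Bdnf, a neurotrophin gene with an exon opposite another gene, at 0.45 ± 0.185. Of the rapid immediate early genes, 17 of 19 were above 0, with a median of 0.26 (camera adjusted p = 4.58e-05, and adjusted p = 0.21 with an estimated correlation). The nuclear receptor gene Nr4a1 was at 0.94 ± 0.290, the AP-1 gene Fosb at 0.73 ± 0.293 and the zinc finger gene Egr1 at 0.54 ± 0.229. No member passed over all genes tested in this edgeR fit, with edgeR adjusted p = 1 for each gene named. Under the alternatives Nptx2, Bdnf, Nr4a1, Fosb and Egr1 each passed in 1, and Nr4a3 in 0. Adjusted over the list alone, 1 rapid and 0 delayed genes passed. In naive mice the rapid list had a median genotype effect of 0.49 (camera adjusted p = 0.145) and the delayed list of -0.02 (0.999). The interaction at 4 h passed for neither list, with medians of -0.12 for the rapid (camera adjusted p = 0.607, with the test itself pointing up) and 0.27 for the delayed list (0.124, and adjusted p = 0.781 with an estimated correlation). The interaction of the delayed list did pass with an additive cohort term, by limma, with no filter and with the replicate block, and without WT naive replicate 4 or Shank3 4 h replicate 6 (medians less that of all genes 0.36 and 0.34). Against 0.28 with all libraries, that median was 0.12 without WT naive replicate 7 and 0.19 without Shank3 naive replicate 4 or Shank3 4 h replicate 1, where the list did not pass. Ribosomal protein, oxidative phosphorylation and postsynaptic density genes had medians of 0.16, 0.17 and 0.11 (camera adjusted p = 0.00179, 0.0168 and 0.0182), and adjusted p = 0.583, 0.743 and 0.583 with an estimated correlation. In the fit with the pair share these lists had camera adjusted p = 0.749, 0.36 and 0.129, and the oxidative phosphorylation median less that of all genes turned from 0.17 to -0.02. These 3 lists also lost their calls without single libraries: oxidative phosphorylation without WT replicates 1 or 2 or Shank3 replicates 1, 3 or 5, postsynaptic density without WT replicate 2 or Shank3 replicates 1 or 3, and ribosomal protein without WT replicate 2 or Shank3 replicate 3. Without single libraries their medians less that of all genes ran from 0.05 (without Shank3 4 h replicate 5) to 0.36 for oxidative phosphorylation, from 0.07 (without Shank3 4 h replicate 3) to 0.38 for ribosomal protein and from 0.04 (without WT 4 h replicate 2) to 0.18 for postsynaptic density genes, each highest without WT 4 h replicate 5.

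**Figure D4:**
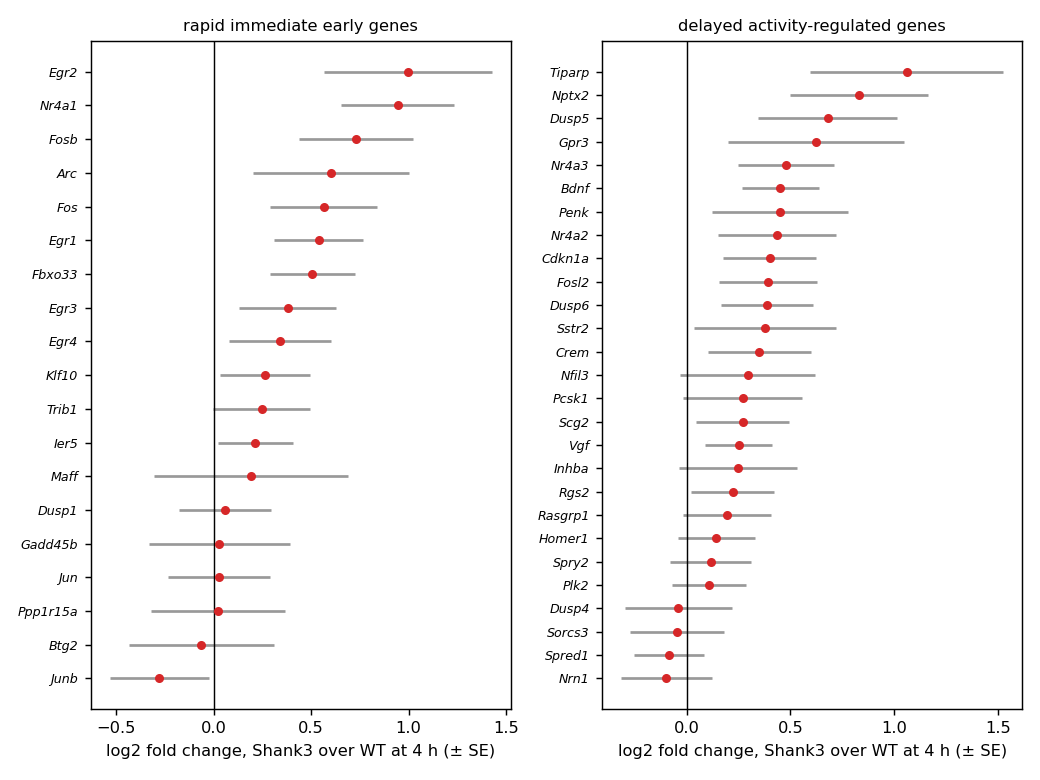
Log2 fold change of Shank3 over WT mice at 4 h for the measured members of the rapid immediate early and delayed activity-regulated lists, with bars of 1 SE. Points above 0 number 17 of 19 and 23 of 27.

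In the average over all conditions Ncam2 was the only gene past the threshold, with a log2 fold change of 1.34 ± 0.218 (SE, edgeR adjusted p = 0.00305, and 2.09 without WT naive replicate 1), and it rested on the naive mice. The fit with the pair share called 2, limma 3 and the fit with no filter 13 genes, and 0 passed with an additive cohort term. The log2 fold change of Ncam2 was 2.43 ± 0.403 in naive mice, 0.25 ± 0.237 at 1 h and 0.24 ± 0.202 at 4 h (adjusted p = 1 for both swim times). The SE of Ncam2 over all conditions is too small as well, since the average holds the naive values with their few counts. In all, 463 genes had an unadjusted p under 0.05. The rapid immediate early genes had a median of 0.27 over 19 members, with 0 past the threshold (camera adjusted p = 0.00852, and adjusted p = 0.94 with an estimated correlation), and lost their call without WT naive replicates 1 or 3 or Shank3 naive replicates 2 or 7, with medians less that of all genes down to 0.19. Of 165 genes tested within 10 Mb of Shank3, 0 passed by edgeR, 5 had an unadjusted p under 0.05 and 1 passed in the fit with the pair share. Ncam2 did not pass without WT naive replicate 2, which left 0 genes, and 2 genes passed without WT naive replicate 3, Shank3 naive replicate 5, WT 1 h replicates 1 or 4, WT 4 h replicate 2, or Shank3 4 h replicates 1 or 3. Taken within each cell, Ncam2 passed in none, and 1 gene passed at 4 h.

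The swim response at 1 h in WT mice included some of the genes that neurons induce within minutes of activity, though the list of them did not pass. Fos, an AP-1 transcription factor gene (ENSMUSG00000021250, chromosome 12 from 85473890 to 85477273), rose from 3.02 ± 1.91 CPM (SD, n = 3) to 27.8 ± 10.1 CPM (n = 6), a log2 fold change of 3.26 ± 0.57 (SE, edgeR adjusted p = 0.000423). Arc, an effector of synaptic plasticity, rose by 3.39 ± 0.766 (adjusted p = 0.00219, and by 5.0 without WT naive replicate 2), Nr4a1 by 3.17 ± 0.659 (adjusted p = 0.00116) and Egr1 by 1.72 ± 0.325 (adjusted p = 0.00062). Of 19 rapid immediate early genes 9 rose and 2 fell, and 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0616, 0.68 with an estimated correlation and 0.47 in the fit with the pair share, but past 0.05 without WT naive replicate 2, WT 1 h replicates 4 or 6, Shank3 naive replicate 4 or Shank3 4 h replicate 6). Of 27 delayed activity-regulated genes 7 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.255). Plk2, a kinase of synaptic scaling, rose by 1.79 ± 0.271, Nr4a3 by 2.01 ± 0.494, Spred1, an inhibitor of Ras signalling, by 1.19 ± 0.288 and Rasgrp1 by 1.13 ± 0.286. Fos, Arc, Nr4a1, Egr1, Nr4a3, Plk2, Spred1 and Rasgrp1 have no gene on the opposite strand in the annotation. That does not make their values certain, since their counts may be the residue of counting on the opposite strand.

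Among the other groups at 1 h in WT mice, the oxidative phosphorylation list passed and the others named here did not, while 1917 of all 11341 genes were higher and 1962 lower. Of 20 heat shock and chaperone genes 8 rose and 1 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.105), with Hspa4, Hspa8 and Fkbp4 up by 1.01 ± 0.209, 1.05 ± 0.246 and 1.23 ± 0.269. Of 42 postsynaptic density genes 12 rose and 3 fell, among them the glutamate receptor gene Gria2, up by 1.10 ± 0.251, and Dlg1, up by 0.89 ± 0.197 (camera adjusted p = 0.0616). Of 30 presynaptic vesicle genes 8 rose and 2 fell, with Syn2 up by 1.58 ± 0.282 (camera adjusted p = 0.068). Of 59 oxidative phosphorylation genes 23 rose and 1 fell (median 0.84, camera adjusted p = 0.000411, and adjusted p = 0.68 with an estimated correlation), with Cox6c up by 1.88 ± 0.301. In the fit with the pair share the oxidative phosphorylation list did not pass (median 0.43, adjusted p = 0.175) and the chaperone list did, with 11 higher and 1 lower (adjusted p = 0.0428, and 0.802 with an estimated correlation). Ribosomal protein genes rose in 18 and fell in 4 of 64 (camera adjusted p = 0.0616). The counts of these 4 lists were the same adjusted over the list alone. The circadian output genes Hlf and Bhlhe40 rose by 1.14 ± 0.309 and 1.35 ± 0.352, and 5 of 19 clock genes rose and 1 fell (camera adjusted p = 0.0711). Pde1a, a phosphodiesterase gene, rose by 1.65 ± 0.232, the transcription factor gene Neurod2 fell by 0.78 ± 0.210 on the log2 scale, and Fam20c and Tmem121b fell by 1.90 ± 0.319 and 1.25 ± 0.222. These single genes had edgeR adjusted p of 0.0061 or less. Syn2, Cox6c and Bhlhe40 have an exon opposite another gene and their values are uncertain for that reason. Dlg1 was not in the fit on genes with no opposite-strand gene, so a gene on the opposite strand may bear on its counts. Neurod2 did not pass without WT naive replicate 1 (-0.54) nor Bhlhe40 without WT naive replicate 2 (1.03).

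In all, 3879 genes passed for WT mice at 1 h, 1917 higher and 1962 lower. Among genes with an exon opposite another gene 582 were higher and 1629 lower, and among genes with none 1040 were higher and 268 lower. The fit with the pair share called 2461 genes, 1413 higher and 1048 lower, of which 2127 were called in the same direction in both fits, and it called all 22 named genes. Restricted to genes with no opposite gene, that fit called 553 genes and not Arc (adjusted p = 0.0864). The log2 fold change of Arc was between 2.775 and 3.812 over 12 alternatives. The count fell to 2568, 2577 and 2325 without WT naive replicates 1, 2 and 3, and to 2110 with the glial score.

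In Shank3 mice at 1 h Fos rose from 2.46 ± 2.53 CPM (SD, n = 3) to 24.1 ± 3.16 CPM (n = 5), a log2 fold change of 3.16 ± 0.552 (SE, edgeR adjusted p = 0.000709), and of 4.25 without Shank3 naive replicate 1. Nr4a1 rose by 3.06 ± 0.672 (adjusted p = 0.00758), Egr1 by 1.10 ± 0.311 (adjusted p = 0.0248), Nr4a3 by 1.97 ± 0.433 and Plk2 by 1.03 ± 0.251. Of the rapid genes 4 rose and 1 fell, Trib1, by 1.16 ± 0.307 on the log2 scale, with the same counts adjusted over the list alone (camera adjusted p = 0.339, past 0.05 without Shank3 naive replicate 2). Of the delayed genes 5 rose and 1 fell, and 6 and 3 adjusted over the list alone (camera adjusted p = 0.318). The chaperone genes Dnajb1 and Hsp90aa1 rose by 1.10 ± 0.307 and 0.83 ± 0.263, and the endoplasmic reticulum stress genes Manf and Atf4 by 1.46 ± 0.356 and 1.15 ± 0.336. Bhlhe40, Cox6c and Rps23 rose by 1.48 ± 0.340, 1.79 ± 0.279 and 0.93 ± 0.251, Dlg1, Syn2 and Mef2c by 0.58 ± 0.190, 0.95 ± 0.272 and 0.67 ± 0.224, and Cnnm2 and Zmat3 fell by 1.12 ± 0.227 and 0.94 ± 0.202 on the log2 scale. Syn2, Cox6c and Bhlhe40 have an exon opposite another gene, so their values are uncertain. Manf and Dlg1 were not in the fit on genes with no opposite-strand gene, so a gene on the opposite strand may bear on their counts. Oxidative phosphorylation genes were the only list past the threshold (median 0.42, 2 higher and 1 lower of 59, 1 and 0 adjusted over the list alone, camera adjusted p = 0.0173, and adjusted p = 0.759 with an estimated correlation), and did not pass without Shank3 1 h replicate 3 or in the fit with the pair share (median 0.14, adjusted p = 0.553).

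In all, 1388 genes passed for Shank3 mice at 1 h, 566 higher and 822 lower, and the fit with the pair share called 1361 and all 18 named genes. The count rested on few libraries. It was 883, 58 and 205 without Shank3 naive replicates 1, 2 and 3, and 810, 254, 766 and 910 without Shank3 1 h replicates 2, 3, 4 and 5. Fos, Nr4a3 and Cox6c passed without each of these libraries in turn, while the other 15 named genes, Nr4a1 and Plk2 among them, did not pass without Shank3 naive replicate 2. When single libraries were left out the log2 fold change of Nr4a1 ran from 2.73 to 3.29 and that of Plk2 from 0.96 to 1.09, so these calls ended with little change in the fold. Egr1 did not pass without Shank3 naive replicates 1, 2 or 3 or Shank3 1 h replicate 3. Its log2 fold change ran from 1.03 to 1.26 when single libraries were left out.

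**Figure D5:**
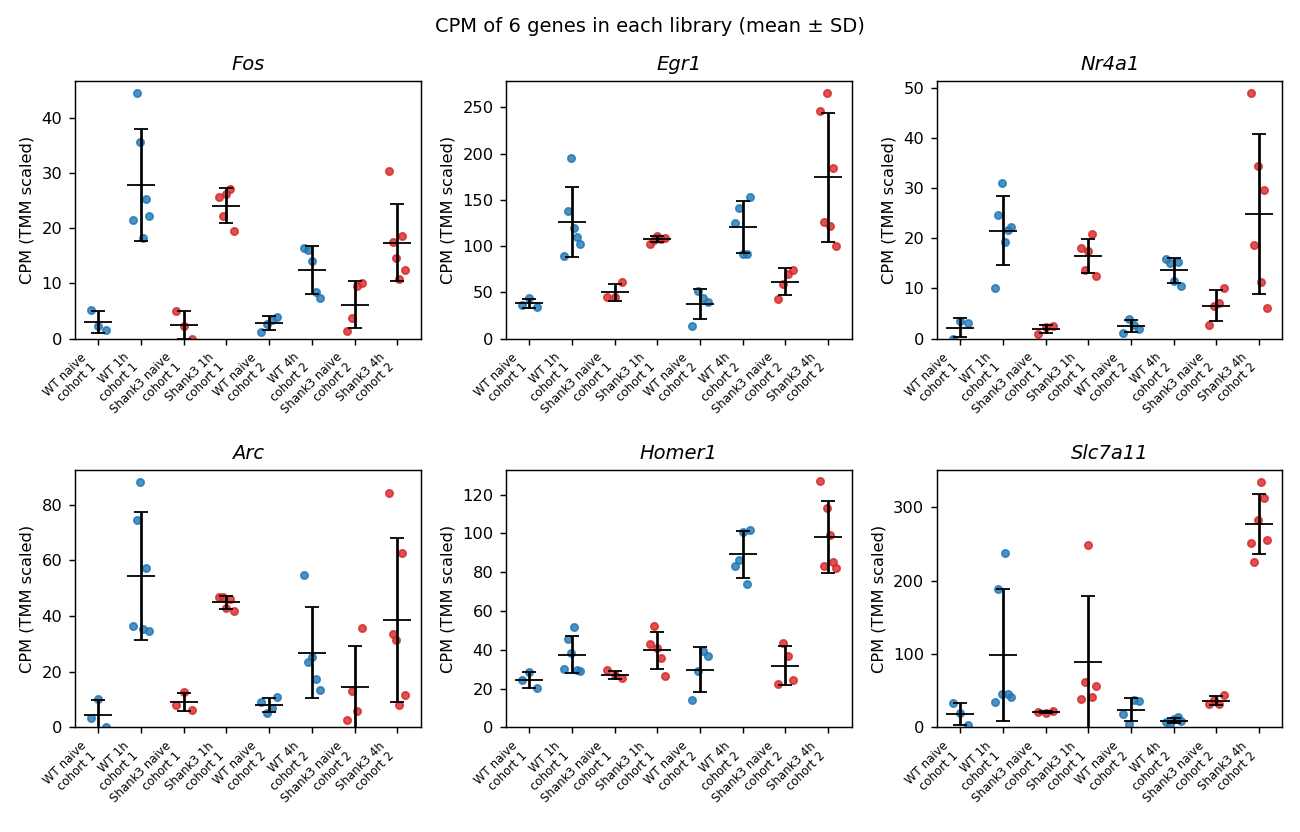
CPM (vertical axes) of Fos, Egr1, Nr4a1, Arc, Homer1 and Slc7a11 in each library, by group and cohort, with TMM scaling and bars for the mean ± SD. Fos rose at 1 h to 27.8 CPM in WT and 24.1 CPM in Shank3 mice, Homer1 at 4 h to 89.3 and 98.3 CPM, and Slc7a11 at 4 h was at 9.02 and 276.9 CPM.

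At 4 h in WT mice, the delayed activity-regulated gene Homer1, a postsynaptic scaffold (ENSMUSG00000007617, chromosome 13 from 93299635 to 93405129), rose from 29.8 ± 11.5 CPM (SD, n = 4) to 89.3 ± 12.0 CPM (n = 5). Its log2 fold change was 1.56 ± 0.235 (SE, edgeR adjusted p = 5.26e-06). Plk2 rose by 1.56 ± 0.220, Spred1 by 1.26 ± 0.215 and Egr1 by 1.68 ± 0.285, and Vgf, a neuropeptide precursor, fell by 1.04 ± 0.183 on the log2 scale. Mal2 and Snap91 rose by 2.95 ± 0.431 and 1.88 ± 0.276, and Xbp1, a transcription factor of the unfolded protein response, by 2.42 ± 0.368. Cenpb, Ankrd24 and Neurod2 fell by 2.08 ± 0.239, 1.82 ± 0.228 and 0.86 ± 0.2, and Hsp90ab1 by 1.23 ± 0.230, on the log2 scale. With Hlf, up by 1.36 ± 0.250, these 13 of 24 named genes also passed in the fit with the pair share. Homer1 was at 1.07 in that fit (adjusted p = 0.00181). The other 11 did not pass there, among them Nr4a1 (2.43 ± 0.543, then 1.47), Egr3 (1.5 ± 0.331, then 0.39), Per1 (1.74 ± 0.542, then 0.02) and the vesicular glutamate transporter gene Slc17a7 (1.29 ± 0.258, then 0.23).

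Group by group at 4 h in WT mice, 10 of 19 rapid immediate early genes rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.176) and 10 of 27 delayed genes rose and 3 fell (camera adjusted p = 0.109). Of 16 glucocorticoid-responsive genes 8 rose and 4 fell (adjusted p = 0.349), of 20 chaperone genes 6 rose and 5 fell (0.827), and of 15 endoplasmic reticulum stress genes 6 rose and 1 fell (0.153, and 0.0356 in the fit with the pair share, where 3 rose). With an estimated correlation the endoplasmic reticulum stress list did not pass in the fit with the pair share. Of the 2 cold-inducible genes 1 fell (0.349). The 5 lists that follow passed, but had an adjusted p of 0.448 with an estimated correlation. Clock genes rose in 11 and fell in 1 of 19 (0.0209), postsynaptic density genes rose in 17 and fell in 4 of 42 (0.0393) and presynaptic genes rose in 17 and fell in 3 of 30 (0.0393). Ribosomal protein genes rose in 33 and fell in 8 of 64 (0.00533) and oxidative phosphorylation genes rose in 40 and fell in 2 of 59 (2.64e-05). In the fit with the pair share no more than 2 members of each of these 5 lists rose, or 6 clock genes adjusted over the list alone, and none of the 5 passed (adjusted p from 0.8 to 0.913). In the fit without the covariate, adjusted over the list alone the counts were 9 and 4 for glucocorticoid, 5 and 1 for endoplasmic reticulum stress, 34 and 8 for ribosomal protein and 41 and 2 for oxidative phosphorylation genes, and the other counts of these response lists were the same. The postsynaptic and presynaptic lists did not pass without WT naive replicate 4 (medians less that of all genes 0.26 each) or WT 4 h replicate 5. Among cell type markers, pyramidal genes rose in 4 and fell in 2 of 10, upper-layer genes rose in 3 of 9 and deep-layer genes in 3 of 9. Astrocyte genes rose in 3 of 6, oligodendrocyte genes in 3 of 4 and thalamic genes in 1 of 3. Microglia genes fell in 1 of 2 and inhibitory neuron genes in 1 of 4, and of 5 striatal genes 1 rose and 1 fell. None of these cell type lists passed, with camera adjusted p from 0.103 for oligodendrocyte to 0.827 for striatal and inhibitory markers. The inhibitory median was 0.79 while its test pointed down.

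In all, 6350 genes passed for WT mice at 4 h, 3294 higher and 3056 lower, and 872 passed in the fit with the pair share, 464 higher and 408 lower. Both fits called 719 in the same direction. Among genes with an exon opposite another gene 957 were higher and 2371 lower, and among genes with none 1852 and 557. The pair share and the glial score were higher at 4 h than in naive mice, and with the glial score as covariate 860 genes passed, 264 higher and 596 lower.

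In Shank3 mice at 4 h Homer1 rose from 31.7 ± 9.97 CPM (SD, n = 4) to 98.3 ± 18.6 CPM (n = 6), a log2 fold change of 1.59 ± 0.229 (SE, edgeR adjusted p = 1.87e-06, and 0.0228 in the fit with the pair share). Spred1 rose by 1.47 ± 0.216, Etv5, an ETS factor gene, by 2.24 ± 0.302 and Rasgrf1 by 2.03 ± 0.259, and Ankrd24 fell by 1.87 ± 0.220 on the log2 scale. These 5 of 25 named genes passed in both fits. The other 20 passed only without the covariate, among them Plk2 at 1.33 ± 0.211, Egr1 at 1.51 ± 0.269, Fosb at 2.13 ± 0.473 (3.06 without Shank3 naive replicate 5), Per1 at 2.85 ± 0.529, Xbp1 at 2.09 ± 0.333 and Slc17a7 at 1.39 ± 0.251. Of the delayed genes 17 of 27 rose and 2 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.00917, and 0.00286 in the fit with the pair share, where 2 rose, with adjusted p = 0.197 there with an estimated correlation). With an estimated correlation and no covariate the adjusted p was 0.45 for the delayed list and for each of the 5 lists that follow. Clock genes rose in 14 and fell in 1 of 19 (0.00763), postsynaptic density genes in 21 and 3 of 42 (0.00917) and presynaptic genes in 17 and 5 of 30 (0.00917). Ribosomal protein genes rose in 40 and fell in 6 of 64 (0.00052) and oxidative phosphorylation genes rose in 44 and fell in 2 of 59 (5.15e-06). Adjusted over the list alone 18 and 5 presynaptic, 41 and 6 ribosomal protein and 45 and 2 oxidative phosphorylation genes rose and fell. In the fit with the pair share these 5 lists lost their calls. The median of ribosomal protein genes went from 1.25 to 0.08 (adjusted p = 0.938) and that of oxidative phosphorylation genes from 1.33 to 0.12 (0.592), with clock genes at 0.138, postsynaptic density genes at 0.77 and presynaptic genes at 0.592, and 1 postsynaptic density gene was the only member to pass. In all, 7040 genes passed, 3711 higher and 3329 lower, and 60 passed in the fit with the pair share, 51 of them in the same direction in both fits. The pair share and the glial score were higher here too, and with the glial score as covariate 1719 genes passed, 566 higher and 1153 lower.

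The responses of the genotypes were compared directly, since the series title names an altered response as its subject. At 1 h the log2 fold changes of both genotypes correlated across 11341 genes at r = 0.665, and at r = 0.8 with a slope of 0.555 over genes called in either. Both genotypes called 424 genes higher and 737 lower, where independent lists would share 95.7 and 142.2, and 1 gene was called in opposite directions. At 4 h r was 0.898 over all genes and 0.914 over called genes, with a slope of 0.989, and 2696 and 2780 genes were shared against 1077.9 and 897. In the fit with the pair share r over all genes was 0.543 at 1 h and 0.629 at 4 h, and over called genes 0.744 and 0.913 with slopes of 0.55 and 0.633. The shared genes there were 444 higher and 559 lower at 1 h against 76.5 and 69, and 35 and 18 at 4 h against 1.7 and 0.7. In that fit both responses use the same estimated slope of each gene on the pair share. Error in the slope enters both alike, so some of the agreement and overlap there is built in. Genes are not independent replicates, so no p is given for these correlations. The slopes are of Shank3 on WT values. At 1 h, and at 4 h with the pair share, most called genes were called in WT mice. Selection and error in the WT values can lower such slopes, so they do not measure a weaker Shank3 response. The interaction tests called 0 genes by edgeR at 1 h, with 468 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma. They called 0 at 4 h, with 302 at an unadjusted p under 0.05, 1 by DESeq2, higher, 1 by limma, lower, and 5 by edgeR with no filter. Slc7a11 had the interaction with the smallest p at 4 h, at 4.37 ± 0.817 (SE, edgeR adjusted p = 0.0615, from 8.8e-29 to 0.583 over 11 alternatives). It passed without any 1 of WT naive replicates 3 and 5, each of the 1 h libraries except Shank3 replicate 2, and WT 4 h replicate 4. At 1 h Atp6v0b and Acat2 were at -1.33 ± 0.306 and -2.30 ± 0.535 (adjusted p = 0.392), and 2 genes passed without WT naive replicate 3.

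The difference between the 4 h and 1 h responses, averaged over the genotypes, passed for 1401 genes, 424 higher and 977 lower, and with DESeq2 size factors for 536 higher and 671 lower. Higher at 4 h were Dlgap4 and Shank2, postsynaptic scaffold genes, at 1.80 ± 0.333 and 1.37 ± 0.259 (SE), Smad3 at 1.14 ± 0.219 and Cobl at 1.26 ± 0.236, each with an edgeR adjusted p of 0.000806 or less. Lower were Araf at -2.31 ± 0.255, Adam17 at -3.59 ± 0.467 and Amt at -1.94 ± 0.310. Naive mice of the cohorts also differed for these, with log2 values of cohort 2 over cohort 1 of 1.26 ± 0.203 for Araf, 2.57 ± 0.433 for Adam17 and 1.41 ± 0.270 for Amt (edgeR adjusted p = 0.000264, 0.000441 and 0.00174). Dlgap4, Araf and Adam17 have an exon opposite another gene and their values are uncertain. Shank2 and Cobl were not in the fit on genes with no opposite-strand gene, so a gene on the opposite strand may bear on their counts too. Between the naive cohorts, a comparison chosen after the values were seen, 1208 genes passed. The naive libraries enter this comparison and the difference with opposite signs, so opposite values of the same gene are partly built in. Time and cohort cannot be told apart here, since each swim time was taken in 1 cohort. Presynaptic, oxidative phosphorylation and oligodendrocyte lists were higher (camera adjusted p = 0.0171 each), as were ribosomal protein (0.0233) and postsynaptic density genes (0.0493), and cold-inducible genes were lower (0.046), with adjusted p from 0.441 to 0.606 with an estimated correlation. Without WT naive replicate 2 the presynaptic list alone of these 6 still passed. The fit with the pair share called 705 genes and none of these lists, and the count was 626 with the glial score and 917 without the 3 libraries high in the ribosomal RNA row.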

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

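The tests of the strand explanations and of Fos, Nr4a1, Egr1 and Arc were chosen after the results were seen, as were the pair share test of the activity lists and the count of splits over any list. The slope test was set before its own value was seen, on a pair share that was defined after the results were seen. The tests without 1 library and the other counts of splits were set before their values were seen.

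Libraries that stood apart from their group numbered 7 of 78 groups tested, where chance gives about 3.9. Acat2 stood apart at 20.11 CPM in Shank3 4 h replicate 1 and at 17.31 CPM in WT naive replicate 4. Arc was at 54.71 CPM in WT 4 h replicate 1. Ncam2 was at 12.59 CPM in WT 1 h replicate 1. Slc7a11 was at 249.0 CPM in Shank3 1 h replicate 3. WT 4 h replicate 5 held 3.52 M counts, the highest total. The ribosomal RNA row held 10.54% of the counts in WT 1 h replicate 5, and 38.58% and 13.52% in Shank3 naive replicates 7 and 6, which did not stand apart by the same measure. The swim response differed between 4 h and 1 h for 1401 genes by a test of the difference itself.

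Counts lay mostly on rows with an exon opposite another gene. A strand-preserving kit counted with the opposite setting is a candidate explanation, since the antisense row was above its partner in 757 of 999 pairs. Counting that ignored the strand argues less well, since the coding partner would then keep its own exons, and the median antisense percent was 82.0%. No biological explanation was tested, because both genotypes and naive mice show the pattern. Counts on genes such as Fos that have no opposite gene may then be the residue on the other strand, which was not tested.

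Between 6350 and 7040 genes were called at 4 h along with a shift in the strand mix. The slope of each gene on the pair share, taken from cohort 1 alone, correlated across genes with the WT response at 4 h, which used none of those libraries, at r = 0.763, so the strand mix is a candidate source of most of these calls. With the slope from cohort 2, r was 0.533 for the WT and 0.459 for the Shank3 response at 1 h, so it may bear on calls at 1 h too. In simulated libraries that differed only along the pair share, with slopes fitted to these same data, both responses at 1 h gave 0 calls without the covariate. The part of the strand mix in the calls at 1 h thus stays open. A response to the swim that changes the pair share cannot be excluded, since the pair share moved with the swim groups. The rise of Fos, Nr4a1, Egr1 and Arc at 1 h in WT mice argues against the strand mix as its whole cause, because 4 of the 4 genes passed with the pair share as covariate. The glial score rose too at 4 h, and with it as covariate 860 genes passed in WT and 1719 in Shank3 mice. Genes with no opposite gene also rose there, with a median log2 fold change of 0.576 in WT and 0.619 in Shank3 mice. The score is thus not shown to measure glial RNA apart from the strand mix, and its part in these calls stays open.

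The activity lists were higher in Shank3 than in WT mice at 4 h. The strand mix argues against itself as the whole cause, since the delayed list kept an adjusted p of 0.000566 with the pair share and an estimated correlation. No single library carried it, as the highest adjusted p without 1 of the 11 libraries was 0.000109. That does not exclude a difference carried by several libraries of the group. Of 100 splits of these libraries 2 gave a result as large (9.14 on the -log10 p scale, with 10.59 the highest of the others), but the list was picked for its small p. When any list could give the smallest p, 5 of 100 splits gave one as small (9.14, with 10.59 the highest and 5.64 the median of the others), so chance could not be excluded. The median of 5.64 also means that p values with the preset correlation come out small in arbitrary splits of these libraries. A higher level of activity-induced RNA in Shank3 mice at 4 h is a hypothesis found and tested on the same data. The difference was not shown to depend on the swim, since the interaction of the delayed list had an adjusted p of 0.124 and passed only under some alternatives. The median of the delayed list less that of all genes was 0.349 with the glial score as covariate (adjusted p = 1.98e-06) and 0.318 with the Xist level (adjusted p = 2.81e-08), against 0.288 without, and the adjusted p ran from 9.12e-10 to 0.00303 over the alternatives other than single libraries left out. The glial score had an exact p of 0.3961 between the genotypes at 4 h. The median of the delayed list thus did not shrink with either covariate. The adjusted p values with these covariates used the preset correlation, and the Xist row may share the strand uncertainty, so they do not decide. Glial RNA, sex, handling and the mix of neuron types stay open.

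Other splits were drawn for each count. For the WT response at 1 h 2 of 84 splits called as many genes (3879 in the real one, 4057 in the highest other), and for the Shank3 response at 1 h 1 of 56 did (1388 and 5). For WT at 4 h 1 of 100 drawn from 126 possible splits did (6350 and 6187), and for Shank3 at 4 h 1 of 100 drawn from 210 (7040 and 6142). The real split is counted in each. Few splits called as many in these comparisons. In all but Shank3 at 1 h, another split called nearly as many or more. These counts alone thus do not tell a swim effect from a structure of the samples, which was not tested. For the difference of 4 h and 1 h 2 of 100 did (1401 and 2298). Chance could not be excluded for the counts of the genotype effects in naive mice, with 18 of 100 (1 and 13), at 4 h, with 11 of 100 (1 and 4688), and over all conditions, with 6 of 100 (1 and 11). The count of 1 at 4 h does not bear on Slc7a11 itself, whose adjusted p was 1.62e-05 at the highest over 11 alternatives. The genotype effect at 1 h (0 and 74) and the interactions at 1 h (0 and 10) and 4 h (0 and 2517) had a real count of 0, which each of the 100 splits reaches, so these splits say nothing about chance. Whether the splits with 4688 and 2517 calls reflect a structure of the samples was not tested.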

How the results depend on the processing

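The pair share covariate, its use on genes with no opposite-strand gene, and the removal of libraries high in the ribosomal RNA row were chosen after the results were seen. The cause of a change was not tested unless given. Shallow libraries (0.884 M counts at the lowest) limit the power for weakly expressed genes. With an additive cohort term 0 genes passed for the naive genotype effect, 0 over all conditions, 2905 for Shank3 at 1 h and 1 for the 4 h interaction, and r between the genotypes' responses was 0.938 and 0.936. With only the contrast's libraries the counts were 0 (naive), 2929 (Shank3, 1 h) and 1 (4 h interaction). DESeq2 size factors gave 2 over all conditions and the Wald test 3, with 1 for the 4 h interaction. Limma gave 2 (naive), 2787 (4 h genotype), 3 (all conditions), 2877 (Shank3, 1 h), 1 for each interaction and 3645 for the difference of 4 h and 1 h. No filter gave 7, 1, 5 and 13 for the genotype effects in naive mice, at 1 h, at 4 h and over all, 5 for the 4 h interaction, and 77 list tests against 27. Without the filter, lists that had too few measured members could enter, so the 77 may not be out of the same 220 tests.

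With the glial score 2 genes passed over all conditions, 2110 and 860 for WT at 1 h and 4 h, 1719 for Shank3 at 4 h and 626 for the difference. Xist gave 2 over all conditions and 1 for the 4 h interaction. With an estimated correlation the rapid list at 4 h had a median less that of all genes of 0.258 (adjusted p = 0.21) and 1 list test passed. With the pair share 3, 3 and 2 genes passed for the genotype effects in naive mice, at 4 h and over all, 2461 and 872 for WT at 1 h and 4 h, 60 for Shank3 at 4 h, 705 for the difference and 9 list tests, and r at 1 h over called genes was 0.744. On genes with no opposite-strand gene these were 0, 0 and 0, then 553, 196 (Shank3, 1 h), 161, 9, 118 and 9. Here the smaller gene set is part of the cause. Without libraries high in ribosomal RNA 917 passed for the difference. Each cohort alone gave 0 in naive mice, and each cell alone gave 0 except 4 h, with 1.

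For the lists below the direction of the camera test changed, and the value given is the median less that of all genes, which kept its sign in several. For Per1 and Camk2a the value is the log2 fold change. The WT response at 4 h comes first. Chaperones were at -0.455 (additive cohort), -0.214 (contrast libraries), -0.258 (no filter), 0.05 (pair share) and 0.159 (no opposite gene), inhibitory markers at 0.78 and striatal at 0.263 (no filter), astrocyte markers at -0.156 (glial score) and -0.157 (no opposite gene). Ribosomal proteins were at -0.03 and -0.075, postsynaptic genes at 0.058 and 0.033 (pair share, then no opposite gene), rapid genes at 0.192, pyramidal markers at 0.092 and Per1 at -0.113 (no opposite gene). In Shank3 mice at 4 h, with no opposite gene, Camk2a was at -0.047, ribosomal proteins at -0.02, postsynaptic genes at 0.017, astrocyte markers at -0.178 and oligodendrocyte markers at -0.258. Postsynaptic genes for WT at 1 h were at -0.119 (no opposite gene). At 4 h between genotypes, oxidative phosphorylation was at -0.017 (pair share). For the difference, oxidative phosphorylation was at -0.019 (glial score), -0.166 (pair share) and -0.093 (no opposite gene), ribosomal proteins at -0.032 and 0.07, and postsynaptic genes at -0.021 (pair share).

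Leaving out single libraries, the counts ran from 0 to 6 (naive genotype), 0 to 0 (1 h), 1 to 1 (4 h), 0 to 2 (all), 2325 to 4612 and 58 to 1704 (WT and Shank3 at 1 h), 5098 to 6701 and 6098 to 7290 (WT and Shank3 at 4 h), 0 to 2 and 0 to 1 (interactions) and 953 to 2063 (difference). The delayed list at 4 h ran from 0.213 to 0.366 and the rapid list from 0.19 to 0.369. List tests past the threshold ran from 24 to 34. Of other results, 104 gene and 81 list values lost and 20 gene and 44 list values gained a call under an alternative. With the replicate block, 493 genes passed for Shank3 at 1 h and 354 for the difference, and no other count moved by over 1.5 times. Same-numbered libraries correlated from -0.547 to 0.735 (median -0.005, 16 of 82 pairs over 0.1, 5 of 36 libraries best with their own number), so they share only a number.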

Other observations

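The tests of Gm15609 and Shank3 were chosen after the results were seen.

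Genes of endoplasmic reticulum stress in Shank3 mice at 4 h rose in 7 and fell in 1 of 15 (6 and 1 adjusted over the list alone), with a median log2 fold change of 0.64 (camera adjusted p = 0.0753). In the fit with the pair share the list passed in Shank3 mice with an adjusted p of 0.000883 and 0 members past the threshold, and in WT mice with an adjusted p of 0.0356 and 3 members higher. With an estimated correlation in that fit the adjusted p values were 0.351 and 0.946. The interaction at 4 h did not pass for this list (median 0.18, camera adjusted p = 0.547). The cold-inducible RNA-binding protein genes fell in 2 of 2 (median -0.96, camera adjusted p = 0.179).

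Gm15609, opposite exon 10 of Shank3, had a log2 fold change of 0.68 in Shank3 mice over all conditions, which did not pass (adjusted p = 0.0577). It passed in 6 of 15 alternatives, with adjusted p from 3.34e-10 to 1.0. If the difference holds, a candidate explanation is more RNA of the Shank3 gene upstream of the deleted part, read on the other strand. The Shank3 row was also higher over all conditions, by 3.8 standard errors, though its own adjusted p was 0.59. It cannot decide this, since it covers the whole gene, was low in all libraries and would itself hold residual counts under that explanation. The strand mix argues against itself as the whole cause, since the log2 fold change of Gm15609 was 0.72 with the pair share (adjusted p = 3.34e-10, the lowest of the alternatives). Variants linked to the locus that change many nearby genes are argued against by the 3.03% of the genes tested within 10 Mb that had an unadjusted p under 0.05. This is a hypothesis found and tested on the same data, and the files used here do not separate the alleles.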
